A study of Mus musculus with 25 samples.

How the data were processed

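The deposited files were count tables of the authors for 14 RNA libraries and MACS2 peak lists of the authors for 8 ATAC-seq and 2 ChIP-seq libraries, 25 samples being labelled in all, with a ChIP input that was not used here. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.36, RNA reads were aligned with STAR 2.5.2b and counted with featureCounts of Subread 1.5.2, ATAC and ChIP reads were aligned with BWA 0.7.12, peaks were called with MACS2 2.1.0, and deepTools 3.3.0 was used for the ChIP data, all on mm10. Per the labels, 4T1 cells were placed in the fourth mammary fat pad of BALB/c mice, tumour and NK cells were enriched by FACS, and ATAC cells were sorted as CD45-negative after 7 days from 400000 injected cells.

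The RNA values were raw counts of the authors for 49315 genes, of which 48970 (99.3%) were matched from gene IDs to symbols. In the deposited peak lists, the p and q columns are -log10 values of the authors, the enrichment column is the fold over background per the file headers, and the pileup column is the signal at the summit per the file headers. Peak heights were compared only within a list.

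Samples, gene lists, the planned tests and alternatives and the named-gene rule were fixed before the data were examined. Limma voom, the -log10 q of 20, the ATAC comparisons between knockout groups, the genes at unadjusted p, the strata of peak strength, the tests of gene lists against bound, gained and lost regions and their background of tested genes, the NK lists without the genes lower in tumour RSF1KO, and most tests of the results weighed at the end were chosen after the data were seen. So were the strata of expression for ATAC regions at changed genes. By that rule, Rnf2 and Rsf1 are reported in every library, then genes past the adjusted threshold with the largest changes, or the 10 with the smallest p where fewer than 5 passed, then up to 4 members of each list with the smallest p. The genes given as shared by both tumour comparisons, and those nearest to the strongest ChIP peaks, were named by rank after the data were seen. Some results are not reported here.

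Counts were normalised by TMM, filtered with filterByExpr at its defaults (minimum count 10, minimum total 15), and fitted in edgeR 4.0.16 (R 4.3.3) by the quasi-likelihood method, with 1 fit for the 6 tumour-cell libraries and 1 for the 8 NK libraries. Calls used a Benjamini-Hochberg adjusted p below 0.05, two-sided. Gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, and with fry. DESeq2 1.42.0 was planned as an alternative, and limma 3.58.1 voom with quality weights was added after the data were seen. Further alternatives were no filter, a stricter filter of 1 CPM in 4 libraries, RLE normalisation, a replicate block, a fit of the compared groups only, and leaving out each library in turn, where a lone library is assumed to vary like those of the other groups. A fold against a group with 0 counts is given as a lower bound with a floor of 3 counts over the group.

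ATAC regions were the merged peaks of all 8 lists. Gained meant a peak in both libraries of a group and in neither of the other, and lost the reverse. RNF2-bound meant a ChIP peak overlapped by at least 1 bp in both replicates, and a gene was bound when such a peak lay within 2000 bp of its start. Alternatives were a 50% overlap, lists of equal length, a -log10 q of at least 5 or 20, windows of 1000 and 5000 bp, and strata of expression or peak strength. Overlap by chance was simulated with unchanged groups against the shared control, in 100 draws for fold changes and 40 for gene counts.

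On simulated tumour-cell data, edgeR recovered 2%, 34%, 70% and 96% of genes changed 2, 4, 8 and 16-fold, with 7 false calls of 108. DESeq2 made 56 false calls of 181 and voom 5 of 103. On simulated NK data the recovery by edgeR was 10%, 82%, 100% and 100%, with 12 false calls of 158. DESeq2 made 58 of 221 and voom 13 of 155. All 200 planted peak changes were found, and 0 of 20 unchanged lists were called. No pair of libraries was identical. A reference genome was not used here, so that GC content was not tested, and reads were not analysed here.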

Results

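Cells of the mouse mammary carcinoma line 4T1, which forms tumours in the mammary fat pad of BALB/c mice, were compared as control cells, as cells labelled RNF2KO or RSF1KO, and as cells labelled with the RNF2 change I53A. RNF2 is the ubiquitin ligase of Polycomb repressive complex 1 (PRC1), RSF1 is a chromatin remodelling factor that binds ubiquitinated histone H2A, and the I53A change impairs the ligase. RNA was counted in 6 libraries of tumour cells in 3 groups, and in 8 libraries of natural killer (NK) cells from tumours in 4 groups, where each knockout had NK cells from its own control tumours. Open chromatin was measured by ATAC-seq in 8 libraries of tumour cells in 4 groups, and RNF2 occupancy by ChIP-seq in 2 libraries of cultured 4T1 cells. Every group held 2 libraries, and the labels do not say that these came from separate animals or cultures, so that the p-values measure only the spread between these samples, which may be technical. The tumour-cell libraries held 19108448 and 17544319 counts in the control, 16169905 and 17040996 in the group labelled RSF1KO, and 12505726 and 17954809 in the group labelled RNF2KO. The NK libraries held 18026854 and 29510766 counts in the control for RSF1KO, 25361497 and 18889560 in the group labelled RSF1KO, 29330455 and 22500062 in the control for RNF2KO, and 25888572 and 20837751 in the group labelled RNF2KO. The series asks what the tumour cells express and open when RNF2 or RSF1 is altered, and what the NK cells of those tumours express.

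At the level of gene counts, neither Rnf2 nor Rsf1, the targeted genes, was below the control in both replicates of its knockout label. In the tumour cells, Rnf2 measured 19.3 and 23.03 CPM (counts scaled to the library total) in the control and 24.9 and 29.3 in the group labelled RSF1KO. In the libraries labelled RNF2KO it measured 8.16 CPM in replicate 1 (95% Poisson interval 6.65 to 9.90) and 54.1 in replicate 2 (50.8 to 57.6), so that replicate 2 stood above every other tumour-cell library. Rsf1 measured 21.5 and 18.6 CPM in the control, 25.5 and 29.0 in the group labelled RNF2KO, and 36.7 (33.8 to 39.8) and 17.4 in the group labelled RSF1KO. In the edgeR quasi-likelihood fit, Rnf2 had a value against the control of 0.14 ± 0.66 (log2 fold change ± SE, n = 2 libraries per group) in the group labelled RNF2KO (Benjamini-Hochberg adjusted p = 0.944), and Rsf1 one of 0.12 ± 0.43 in the group labelled RSF1KO (adjusted p = 0.949). In the NK cells, which came from the host mice, Rnf2 ranged from 61.9 to 160 CPM and Rsf1 from 35.9 to 76.0. The intervals cover counting error only, and a knockout that leaves the transcript in place would not show in a gene count. Each direction below is therefore one between libraries as labelled.

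**Figure D1:**
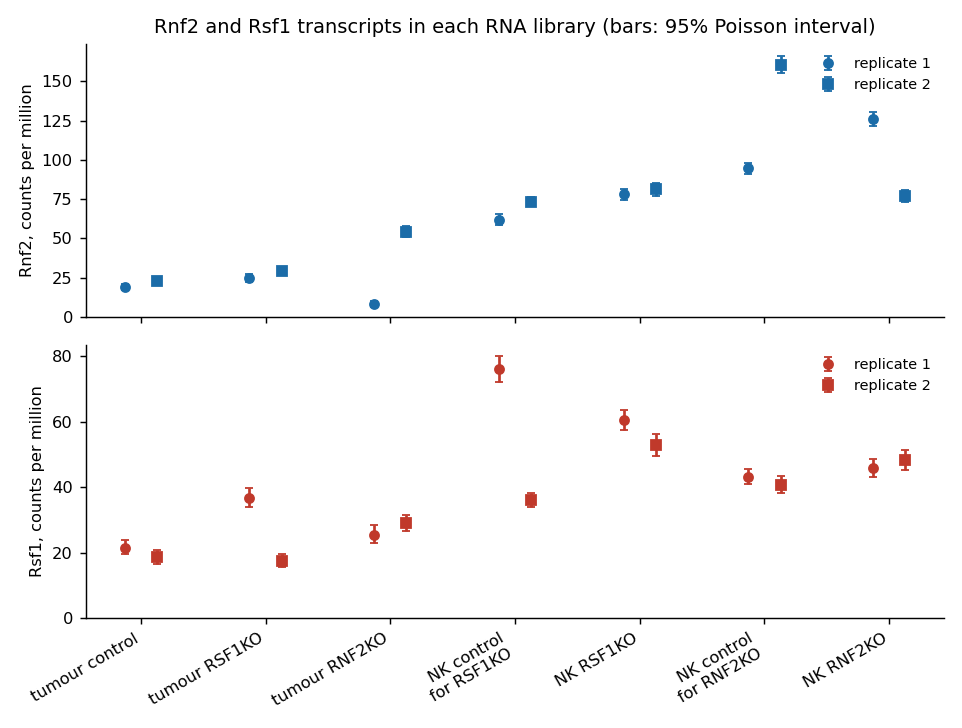
Rnf2 (top) and Rsf1 (bottom) in CPM for each of the 14 RNA libraries, with groups on the x axis, circles for replicate 1, squares for replicate 2 and bars for the 95% Poisson interval. Rnf2 was 8.16 in replicate 1 and 54.1 in replicate 2 of the tumour group labelled RNF2KO, and Rsf1 was 36.7 and 17.4 in the tumour group labelled RSF1KO.

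Transcripts of leukocytes set 1 tumour-cell library apart. In the library labelled RNF2KO replicate 2, the summed level of the T cell markers was 724 CPM, against 18.3 to 28.4 in the other 5 libraries, and that of the NK cell markers was 1108 CPM, against 31.0 to 106. Its macrophage and monocyte markers summed to 3535 CPM, against 324 to 766 elsewhere, while its neutrophil markers summed to 2756 CPM, against 2465 in control replicate 2, where Mmp9 made most of the sum. By member, the neutrophil markers had a median of 31.1 CPM in this library, against 1.58 to 5.43 in the others, and the dendritic markers 10.07 CPM, against 0.39 to 1.75. Lyz2, the lysozyme of myeloid cells, measured 1415 normalised CPM there and 227 in replicate 1, and Nkg7, a granule gene of NK and T cells, measured 310 and 5.90. Fibroblast markers summed to 2529 and 2453 CPM in the libraries labelled RSF1KO, 631 and 802 in the control, and 479 and 1363 in the libraries labelled RNF2KO. Erythroid and platelet markers, mostly globins, differed between replicates, with 21246 and 100 CPM in the group labelled RSF1KO, 6524 and 417 in that labelled RNF2KO, and 4843 and 194 in the control.

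**Figure D2:**
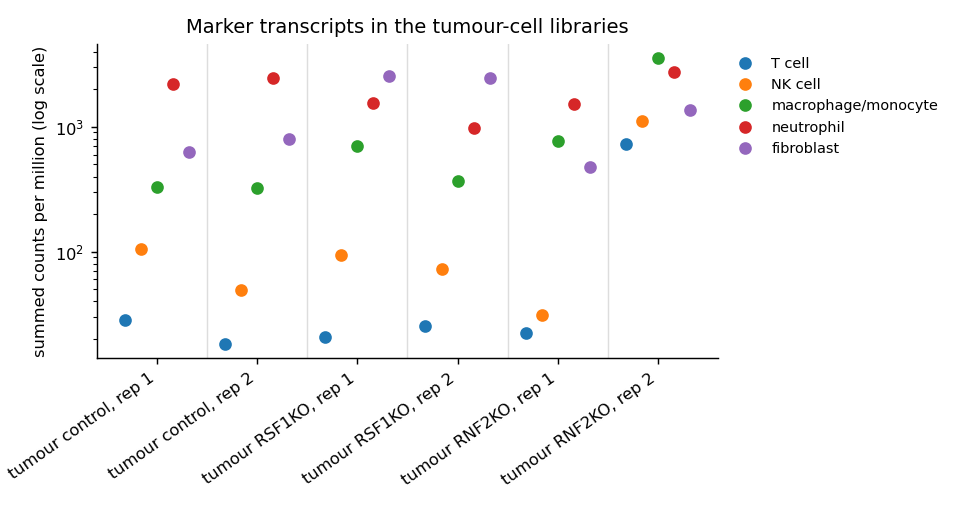
Summed CPM (log scale) of the fixed marker lists of T cells, NK cells, macrophages and monocytes, neutrophils and fibroblasts in each of the 6 tumour-cell libraries. The library labelled RNF2KO replicate 2 held 724 CPM of T cell markers, against 18.3 to 28.4 in the other libraries.

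In the tumour cells labelled RNF2KO, genes of MHC class II presentation and the type I interferon response stood above the control, and hypoxia and cell cycle genes stood below it. H2-Ab1, a chain of an MHC class II molecule that presents peptides to helper T cells, measured 265 and 1726 normalised CPM against 56.5 and 47.7 in the control (4.26 ± 0.82, n = 2 per group, edgeR adjusted p = 0.193). Ifit3, an antiviral gene induced by interferon, measured 161 and 177 against 37.2 and 50.1 (1.96 ± 0.42, adjusted p = 0.226). Car9, the carbonic anhydrase induced by hypoxia, measured 13.8 and 9.51 against 88.2 and 91.8 (-2.95 ± 0.38, adjusted p = 0.155), and Mmp3, a matrix metalloproteinase, 9.40 and 9.51 against 76.7 and 80.6 (-3.06 ± 0.37, adjusted p = 0.155). None of these genes passed the adjusted threshold, and no gene list kept its call with an estimated correlation. Replicate 2 also held the leukocyte transcripts given above, and Rnf2 itself was above the control in it.

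By list, all 10 measured MHC class II genes had positive values in the tumour cells labelled RNF2KO, with a median log2 fold change of 3.03 (camera adjusted p = 1.92e-11; adjusted p = 0.454 with an estimated correlation), and 8 of them rose when adjusted over the list alone. H2-Eb1 and H2-Aa, further class II chains, had values of 3.77 and 3.69. Of 31 type I interferon genes 26 were positive, with a median of 0.73 (camera adjusted p = 8.22e-06; adjusted p = 0.454 with an estimated correlation), and 4 rose when adjusted over the list alone, among them Ifit2 at 2.35. Of 29 chemokine genes 24 were positive, with a median of 1.60 (6.13e-06 by camera; adjusted p = 0.454 with an estimated correlation). Cxcl10, which draws CXCR3-bearing T and NK cells, measured 127 and 201 CPM against 42.6 and 43.4, and Ccl8 had a value of 2.74. The interferon-gamma genes had a median of 0.62 over 26 genes (camera adjusted p = 0.00195; adjusted p = 0.521 with an estimated correlation). These lists moved with the leukocyte markers, whose lists passed camera in the same direction: macrophages 2.79 (2.23e-11), T cells 4.17 (8.22e-06), neutrophils 2.13 (0.00411), dendritic cells 3.74 (0.0134) and B cells 2.28 (0.0153). The adipocyte markers, which are not of leukocytes, passed too at 2.46 (0.0153), and adjusted p = 0.454 with an estimated correlation for each of these marker lists. Leaving out RNF2KO replicate 2 leaves replicate 1 alone, which is then assumed to vary like the libraries of the other groups, so only medians are given. Without it the median was 1.51 for MHC class II, 0.49 for chemokines, 0.29 for interferon-gamma, 0.41 for T cells, 0.91 for macrophages, 0.37 for dendritic cells, 0.41 for neutrophils and 0.67 for B cells. The B cell median, over 4 genes, was 6.04 without RNF2KO replicate 1, 4.66 without control replicate 1 and 6.91 without control replicate 2. Without control replicate 1, the type I interferon median was 0.45. When adjusted over the list alone, 1 interferon-gamma gene, 3 chemokines, 13 of 14 macrophage, 9 of 12 T cell, 5 of 10 neutrophil, 5 of 9 dendritic, 2 B cell and 1 adipocyte genes rose, and 1 neutrophil gene fell.

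Among further lists in the tumour cells labelled RNF2KO, 24 of 27 hypoxia and glycolysis genes had negative values, with a median of -0.84 (camera adjusted p = 2.45e-07; adjusted p = 0.214 with an estimated correlation), and 6 fell when adjusted over the list alone. Ankrd37 and P4ha1, both induced by hypoxia, had values of -1.96 and -1.38, and no single library left out moved the median by more than 1.5 times. All 32 proliferation genes were negative, with a median of -0.93 (camera adjusted p = 3.62e-11; adjusted p = 0.454 with an estimated correlation), with Bub1 and Tpx2, which act at the mitotic spindle, at -2.31 and -1.72. The proliferation median was -1.65 without RNF2KO replicate 1 and -0.49 without RNF2KO replicate 2. The epithelial-mesenchymal list had a median of -0.45 (camera adjusted p = 0.0235; adjusted p = 0.454 with an estimated correlation), where Mmp9 and Mmp14 were at -2.41 and -1.39 and Acta2, smooth muscle actin, at 2.19, and the median was -0.85 without RNF2KO replicate 1, -0.89 without RNF2KO replicate 2 and -0.10 without control replicate 2. When adjusted over that list alone 2 genes rose and 4 fell. The p53 and cell death list had a median of 0.69 (0.0235 by camera; adjusted p = 0.454 with an estimated correlation), led by Casp1, the inflammatory caspase, at 3.66, Casp4 at 2.28 and Cdkn1a, the p21 inhibitor, at 2.03, and 4 genes rose when adjusted over the list alone. Its median was 0.09 without RNF2KO replicate 2 and 0.41 without control replicate 1. The matrix list did not pass at a median of 0.08. The polycomb components (0.10), developmental transcription factors (0.13), MHC class I genes (0.52), inflammatory cytokines (-0.12), NK cell ligands (0.14) and epithelial identity genes (-0.10) did not pass, and neither did the NK (2.82), fibroblast (0.22), endothelial (-0.15) and erythroid (0.25) markers. Smarca5, the remodelling partner of RSF1, measured 91.2 and 53.7 CPM against 204 and 229, and the cytokine Csf3 29.3 and 22.5 against 206 and 79.5.

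No gene of the 16338 tested passed an adjusted p of 0.05 between the tumour cells labelled RNF2KO and the control with edgeR, while 2409 had an unadjusted p below 0.05, with 1505 higher and 904 lower. DESeq2 called 871 genes and limma voom 0. The 10 genes with the smallest p, named as not passing, were Mmp3, Car9, Itga7 (-3.86), Ggt5 (4.10), Ggt1 (3.51), Ifitm6 (4.08), Pigr (3.50), Casp1, Cpq (3.18) and Ly6i (3.82). Leaving out the library labelled RNF2KO replicate 1 gave 1572 edgeR calls, leaving out replicate 2 gave 7, and leaving out either control gave 0. In data simulated for this comparison, edgeR recovered 2% of 50 genes changed 2-fold, 34% at 4-fold, 70% at 8-fold and 96% at 16-fold.

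In the tumour-cell libraries labelled RSF1KO, antigen presentation, interferon, matrix and fibroblast genes stood above the control. Host fibroblasts were not told apart from tumour cells here. H2-Eb1 measured 242 and 274 normalised CPM against 43.7 and 30.4 (2.80 ± 0.70, n = 2 per group, edgeR adjusted p = 0.233). Mmp9, a gelatinase that degrades basement membrane, measured 113 and 162 against 1603 and 2083 (-3.75 ± 0.74, adjusted p = 0.149). Odc1, the first enzyme of polyamine synthesis, measured 31.8 and 22.7 against 238 and 285 (-3.26 ± 0.40, adjusted p = 0.118), and Dcn, a matrix proteoglycan of fibroblasts, 167 and 146 against 47.6 and 33.6 (1.95 ± 0.40, adjusted p = 0.157). None of these genes passed the adjusted threshold, and no gene list kept its call with an estimated correlation. Rsf1 itself was not below the control in both libraries labelled RSF1KO.

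By list, all 10 MHC class II genes were positive in the tumour cells labelled RSF1KO, with a median of 2.31 (camera adjusted p = 9.94e-11), and 8 rose when adjusted over the list alone. Of 21 MHC class I genes 16 were positive, with a median of 0.80 (9.6e-05), led by Nlrc5, the activator of class I genes, at 1.81 and H2-Q7 at 1.59. The type I interferon list had a median of 0.63 (7.58e-07) with Mx1 at 2.07, the interferon-gamma list 0.91 (2.19e-07), and the chemokine list 0.91 (1.46e-05) with Ccl8 at 2.96 and Ccl7 at 2.34. For each of these 5 lists, adjusted p = 0.485 with an estimated correlation. The matrix list had a median of 0.94 (camera adjusted p = 5.62e-05) with Col6a2 at 2.24, and all 12 fibroblast markers were positive with a median of 1.63 (8.23e-09), 7 of them rising when adjusted over the list alone, with Postn at 1.95 and Mfap5 at 1.64 (adjusted p = 0.485 with an estimated correlation for both lists). When adjusted over the list alone, 2 chemokines and 6 matrix genes rose. Macrophage markers had a median of 0.90 (0.00167 by camera; adjusted p = 0.631 with an estimated correlation), and proliferation genes -0.29 (0.0425; adjusted p = 0.860 with an estimated correlation) with Ccna2, an S-phase cyclin, at -1.67. Without RSF1KO replicate 1 the proliferation median was 0.09, the chemokine median 0.50 and the macrophage median 0.46. Without RSF1KO replicate 2 the proliferation median was -0.76 and the type I interferon median 0.41. Without control replicate 1 the chemokine median was 1.45, and without control replicate 2 the matrix median was 1.54 and the proliferation median -0.16. The epithelial-mesenchymal list did not pass at a median of 0.10, though its members Mmp9, Mmp14 (-1.61) and Mmp3 (-1.69) were among 4 that fell when adjusted over the list alone. The remaining medians were -0.24 for polycomb components, 0.00 for developmental transcription factors, 0.14 for inflammatory cytokines, 0.03 for NK cell ligands, 0.15 for epithelial identity, -0.21 for hypoxia and 0.23 for p53 and cell death. Among markers, they were 0.17 for NK, 0.36 for T, 1.05 for B, 0.60 for neutrophils, 1.13 for dendritic, -0.51 for endothelial, 1.85 for erythroid and 1.40 for adipocytes.

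No gene passed an adjusted p of 0.05 between the tumour cells labelled RSF1KO and the control with edgeR. At an unadjusted p below 0.05 there were 1584 genes, 685 higher and 899 lower, and DESeq2 called 496 and limma voom 147. The 10 genes with the smallest p, each at an adjusted p of 0.118, were Odc1, Ldhd (2.86), the transcription initiation factor Taf10 (-3.26), the splicing factor Srsf9 (-2.99), Tmem238 (-3.82), Crtap (-2.67), Cpox (-2.62), the AP-1 subunit Jund (-3.26), the adaptor Grb2 (-2.55) and Rnf187 (-2.91). No single library left out gave an edgeR call.

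Compared directly, the tumour-cell libraries labelled RNF2KO had lower hypoxia, cell cycle, matrix and fibroblast transcripts than those labelled RSF1KO. Host fibroblasts or muscle were not told apart from tumour cells in these libraries, and their share was not tested. Acta1, the skeletal muscle actin, measured 3.58 and 5.52 normalised CPM in the libraries labelled RNF2KO and 85.2 and 78.8 in those labelled RSF1KO (-4.16 ± 0.42, n = 2 per group, edgeR adjusted p = 0.0886). Car9 had a value of -2.88 and Des, the muscle filament desmin, of -5.27, while Jund was at 2.91 and Efhd2 at 2.73 (adjusted p = 0.308 for each). The hypoxia list had a median of -0.54 (camera adjusted p = 3.87e-07; adjusted p = 0.218 with an estimated correlation). Proliferation (-0.67, 1.18e-07), matrix (-0.72, 4.17e-08), fibroblast (-1.17, 5.29e-07) and MHC class I (-0.36, 0.00295) also passed camera, as did the markers of T cells (3.87, 5.76e-07), macrophages (1.69, 5.76e-07), neutrophils (1.44, 0.00237), dendritic cells (2.34, 0.00321) and NK cells (2.61, 0.0375), with adjusted p = 0.705 with an estimated correlation for each. When adjusted over the list alone, 10 T cell markers were higher and 4 hypoxia genes lower. The lists that did not pass were MHC class II (0.91), type I interferon (0.22), interferon-gamma (-0.29), chemokines (0.28), inflammatory cytokines (0.19), NK cell ligands (0.08), epithelial-mesenchymal (0.00), epithelial identity (0.07), p53 and cell death (0.29), polycomb components (0.27) and developmental transcription factors (0.30), and the markers of B (0.93), endothelial (0.28), erythroid (-1.50) and adipocyte (0.36) cells. Leaving out RNF2KO replicate 2 gave medians of -0.14 for T, -1.96 for NK, 0.12 for macrophage, -0.26 for neutrophil and -0.07 for dendritic markers. It also moved proliferation to -0.29, matrix to -1.19 and fibroblasts to -1.95. Leaving out RNF2KO replicate 1 moved proliferation to -1.47, dendritic markers to 3.86 and fibroblasts to -0.74. Leaving out RSF1KO replicate 1 moved MHC class I to -0.56, proliferation to -1.07 and neutrophil markers to 3.37, and leaving out RSF1KO replicate 2 moved them to -0.12, -0.23 and 0.84. No gene passed with edgeR, with 1398 at an unadjusted p below 0.05, 263 called by DESeq2 and 0 by limma voom, and there were 443 edgeR calls without RNF2KO replicate 1 and 4 without replicate 2.

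Of the 16338 genes, 74.8% had the same sign of fold change in the tumour groups labelled RNF2KO and RSF1KO. In unchanged groups simulated against their shared controls it was 66.6% (highest of 100 draws, 67.5%). Without RNF2KO replicate 2 the share was 63.8%, a setting for which no unchanged groups were simulated. Genes with the smallest p in both included Casp1 (3.66 and 2.66), Mmp3 (-3.06 and -1.69), Odc1 (-1.89 and -3.26), the protease inhibitor Timp2 (-2.17 and -2.80), the interferon-inducible Ifi207 (2.82 and 2.60) and the immunoglobulin transporter Pigr (3.50 and 2.35). At an unadjusted p below 0.05, 418 genes were higher in both and 261 lower in both, with 9 in opposite directions, which is 61.02% of the smaller higher list and 29.03% of the smaller lower list. The simulated lists were shorter, with 376 and 384 higher and 378 and 374 lower genes on average, and shared 115 higher genes (highest of 40 draws, 141) and 49.1 lower ones (highest, 65), or 30.5% and 13.1%. Independent lists of the observed sizes would share 63.1 and 49.7. The correlation across genes, which are not independent replicates, was 0.62 against 0.50 in the simulation, and the covariance 0.603 against 0.252. With 1 control library given to each group, so that none was shared, the correlation was 0.40 or 0.38 and the covariance 0.454 or 0.429. With 1 library left out the correlation ran from 0.43 without RNF2KO replicate 2 to 0.68 without control replicate 1. No unchanged groups were simulated for these settings, so 0.50 is not their no-change value. The simulated groups shared their controls too, so the simulated values already hold what shared controls give under that setting. With the controls split, no library was common to both effects, so a shared control cannot give the correlations of 0.40 and 0.38. How far genes that vary together could give them was not simulated.

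In NK cells from tumours labelled RNF2KO, B cell genes and the genes of early activation were lower than in NK cells of their controls, and granzyme C and a set of myeloid genes were higher. Gzmc, a granule protease, rose to 982 and 1245 normalised CPM from 285 and 170 (2.29 ± 0.31, n = 2 per group, edgeR adjusted p = 0.0488). Il7r, the interleukin-7 receptor of lymphocytes and innate lymphoid cells, fell to 17.6 and 21.2 from 114 and 137 (-2.69 ± 0.24, adjusted p = 0.016), and Ccr7, the lymph node homing receptor, to 17.1 and 22.9 from 137 and 148 (-2.83 ± 0.34, adjusted p = 0.031). B cell transcripts fell in the same libraries. A fall of Il7r and Ccr7 within NK cells was therefore not told apart from a smaller share of other lymphocytes. Igkc, the immunoglobulin kappa chain, fell (-5.82 ± 0.55, adjusted p = 0.017), as did Cd79a, a part of the B cell receptor (-4.98 ± 0.44, adjusted p = 0.016). Ms4a1, which encodes CD20, had 0 counts in both libraries labelled RNF2KO and 397 and 238 in their controls, at least 191-fold lower against a floor of 3 counts over the group. Ighg1 was at least 258-fold lower in the same way.

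With edgeR, 23 of 16398 genes passed in NK cells from tumours labelled RNF2KO, 8 higher and 15 lower. The higher genes included Slamf8 (3.71, adjusted p = 0.031), Aif1 (3.51), Adamdec1 (3.28) and Clec12a (2.56), which myeloid cells express, and Igha (2.64). The lower genes included Cd22 (-4.96), Ighd (-3.78), Cxcr5 (-2.52) and Nsg2 (-2.34). DESeq2 called 334 genes, limma voom 0, and a fit of only these groups 0. The count was 432 without RNF2KO replicate 1 and 204 without replicate 2, with all 23 genes among each, and 0 without either control replicate. All 12 B cell markers were negative, 6 of them called over all genes and 10 when adjusted over the list alone, with a median of -4.87 (camera adjusted p = 1.48e-54; adjusted p = 0.00245 with an estimated correlation). Summed B cell markers were 514 and 411 CPM in the controls and 200 and 206 in the libraries labelled RNF2KO. Macrophage markers summed to 2453 and 1189 CPM against 815 and 819, with a median of 2.56 (7.99e-23 by camera; adjusted p = 0.186 with an estimated correlation), 12 of 14 rising when adjusted over the list alone. That median was 1.29 without RNF2KO replicate 1.

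Among NK gene groups, the early activation genes, which respond within hours to receptor signals, had a median of -0.76 in NK cells from tumours labelled RNF2KO (camera adjusted p = 2.07e-14; adjusted p = 0.048 with an estimated correlation), and 13 of 31 fell when adjusted over the list alone. Nr4a1, an orphan receptor induced by antigen receptor signals, measured 1401 and 1100 CPM against 2739 and 3068 (-1.22 ± 0.24, edgeR adjusted p = 0.161), and Junb and Nfkbiz had values of -0.77 and -1.38. Secreted cytokines had a median of -0.52 (camera adjusted p = 0.00101; adjusted p = 0.292 with an estimated correlation) with Tnf at 13.3 and 13.1 CPM against 40.03 and 32.9 (-1.47 ± 0.22). Cytotoxic effectors had a median of 0.33 (0.00101; adjusted p = 0.467 with an estimated correlation), with Gzmb at 5878 and 9124 CPM against 2597 and 2228, Prf1 at 0.33 and Gzmm at -1.46, and the median was 0.04 without RNF2KO replicate 2. Maturation genes had a median of -0.34 (2.44e-05) and inhibitory receptors 0.45 (2.09e-05), for both of which adjusted p = 0.186 with an estimated correlation. Nfil3 and Tbx21, transcription factors of NK development, were at -1.26 and -0.85, and Havcr2, the checkpoint receptor TIM-3, at 2.41. Macrophage markers had a median of 2.56 in the same comparison. Whether Havcr2 and the other inhibitory receptors rose within NK cells or with the myeloid transcripts was not tested. Without RNF2KO replicate 1 the maturation median was -0.62, and without replicate 2 the inhibitory median was 0.04. A set of 835 genes that were lower in the tumour cells labelled RSF1KO at an unadjusted p below 0.05 had a median of -0.64 in this comparison, beyond matched random sets. It held 3 of the early activation genes and 1 maturation gene, and without them those medians were -0.74 and -0.22. T cell markers had a median of -0.44 (2.67e-05; adjusted p = 0.261 with an estimated correlation) and -0.91 without RNF2KO replicate 2. When adjusted over the list alone, 4 effectors and 4 inhibitory receptors rose, and 2 effectors, 3 maturation genes, 2 T cell genes and 1 cytokine fell.

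Chemokines had a median of 1.14 in the same comparison (camera adjusted p = 1.3e-07; adjusted p = 0.261 with an estimated correlation), with Cxcl9 at 2.80 and Ccl22 at -3.10, and the median was 0.03 without RNF2KO replicate 1 and 1.89 without control replicate 1. When adjusted over the list alone 10 chemokines rose and 1 fell. Type I interferon genes had a median of 0.31 (9.84e-05; adjusted p = 0.684 with an estimated correlation) and -0.01 without RNF2KO replicate 1 and 0.64 without replicate 2. Smaller shifts that passed camera were proliferation at -0.21 (0.0198; adjusted p = 0.765 with an estimated correlation), cytokine signalling at -0.09 (0.0318; adjusted p = 0.731 with an estimated correlation) with Cish at 1.02 and Cxcr3 at -1.15, neutrophil markers at 1.46 (0.0009; adjusted p = 0.467 with an estimated correlation) and endothelial markers at 2.11 (0.00838; adjusted p = 0.261 with an estimated correlation). Leaving out RNF2KO replicate 1 moved these to -0.45, -0.26, 0.54 and 1.06, and leaving out RNF2KO replicate 2 moved proliferation to -0.10, cytokine signalling to -0.05 and endothelial markers to 1.13. Leaving out control replicate 1 moved cytokine signalling to -0.32 and neutrophil markers to 3.09, and leaving out control replicate 2 moved them to 0.05 and 0.46. The lists of MHC class I (-0.10), interferon-gamma (0.04), epithelial identity (0.06), hypoxia (-0.05), activating receptors (0.03), ILC1 and residency (0.34) and oxidative phosphorylation (0.07) did not pass. Neither did the NK (0.08), dendritic (0.11, tested as down), fibroblast (0.37) and erythroid (-3.13) markers.

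**Figure D3:**
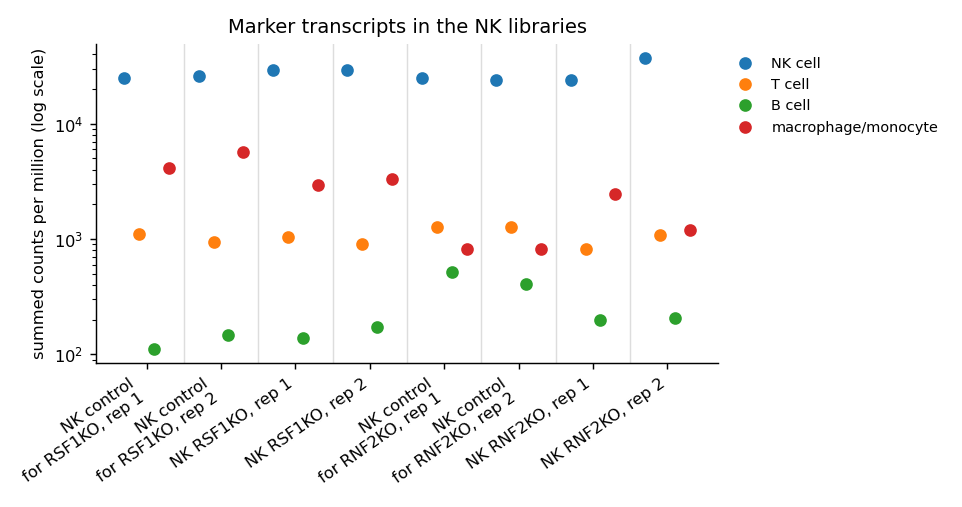
Summed CPM (log scale) of the fixed marker lists of NK cells, T cells, B cells and macrophages and monocytes in each of the 8 NK libraries. B cell markers were at 514 and 411 in the control for RNF2KO and at 112 to 206 in the other 6 libraries.

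In NK cells from tumours labelled RSF1KO, chemokine and respiratory chain genes had negative medians and cytotoxic effector genes a positive one, in 2 libraries against 2, and none of these lists kept its call with an estimated correlation. Ccl7, a monocyte attractant, measured 19.1 and 31.4 normalised CPM against 133 and 125 (-2.35 ± 0.52, edgeR adjusted p = 0.854), and Gzmb 8870 and 7422 against 3449 and 5490 (0.87 ± 0.28, adjusted p = 0.873). The chemokine median was -0.97 (camera adjusted p = 1.9e-15; adjusted p = 0.457 with an estimated correlation). Of 30 oxidative phosphorylation genes 29 were negative, with a median of -0.32 (4.55e-06), 16 of 20 cytotoxic effectors were positive at 0.46 (1.67e-06), and the macrophage median was -0.67 (0.000101), for each of which adjusted p = 0.604 with an estimated correlation. Prf1, the pore-forming perforin, was at 0.65 and Lamp1 at 1.58. The same 835 genes had a median of 0.69 here and held 1 effector, without which the effector median was 0.28. The effector median was 0.25 without control replicate 1 and 0.75 without control replicate 2.

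Further lists that passed camera in NK cells from tumours labelled RSF1KO were epithelial identity at -1.61 (1.67e-06), ILC1 and residency at 0.26 (0.00374), cytokines at -0.29 (0.0148) and early activation at -0.07 (0.0454), for each of which adjusted p = 0.604 with an estimated correlation. Type I interferon was at -0.31 (0.00245; adjusted p = 0.741 with an estimated correlation), cytokine signalling at 0.21 (0.00935; adjusted p = 0.636 with an estimated correlation) and B cell markers at 0.61 (0.00935; adjusted p = 0.457 with an estimated correlation), or 0.43 with genes at 0 set to their bounds. Without control replicate 2 the epithelial median was 0.25, type I interferon 0.06, cytokines 0.02, residency 0.58, cytokine signalling 0.36 and B cells 1.18. Without control replicate 1 type I interferon was -0.59, residency 0.07, cytokine signalling 0.13 and B cells 0.27. Without RSF1KO replicate 1 the epithelial median was -0.91, type I interferon -0.04 and B cells 0.30, and without RSF1KO replicate 2 they were -3.42, -0.61 and 0.94, with residency at 0.09. The early activation median ran from -0.32 without RSF1KO replicate 2 to -0.10 without control replicate 1, with -0.12 without RSF1KO replicate 1 and -0.11 without control replicate 2. Itga1, a residency integrin, measured 91.9 and 93.8 CPM against 22.3 and 43.8, and the checkpoint genes Lag3 and Ctla4 were at 2.70 and 1.83. The lists of MHC class I (-0.10), interferon-gamma (-0.06), proliferation (-0.03), hypoxia (-0.05), activating receptors (-0.02), inhibitory receptors (0.02) and maturation (0.06) did not pass, nor did NK (0.12), T (-0.09), neutrophil (-0.04), dendritic (-0.02), fibroblast (0.14), endothelial (-1.14) and erythroid (-0.48) markers. No gene passed with edgeR, with 881 at an unadjusted p below 0.05, 66 called by DESeq2 and 0 by limma voom. The smallest p belonged to Bcl3, a regulator of NF-kappaB, at 131 and 174 CPM against 42.8 and 44.0 (1.81 ± 0.23, adjusted p = 0.615), followed by the xenobiotic receptor Ahr (1.92), Igha (1.54) and Nfil3 (1.29).

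The controls of the NK experiments differed from each other more than either knockout did from its control. NK cells of the control for RNF2KO held 386 genes that differed from those of the control for RSF1KO with edgeR, 43 higher and 343 lower, against 23 and 0 genes called for the knockouts. B cell genes rose, with Cd79a at 6.57 (edgeR adjusted p = 0.000843) and a list median of 6.38, or 5.53 with genes at 0 set to their bounds (camera adjusted p = 4.06e-37; adjusted p = 0.00433 with an estimated correlation). Il7r measured 114 and 137 normalised CPM against 29.5 and 28.3. Macrophage markers fell with a median of -4.46 (4.69e-36; adjusted p = 0.116 with an estimated correlation), chemokines with -3.22 (5.93e-34; adjusted p = 0.0776 with an estimated correlation), and Ccl24, an eosinophil attractant, measured 3.01 and 2.07 CPM against 277 and 287. F10, coagulation factor X, was at -7.08 (adjusted p = 0.00039), and Il5 had 0 counts in the control for RNF2KO, at least 322-fold lower. The count was 116 without control-for-RNF2KO replicate 1, 72 without its replicate 2, 183 without control-for-RSF1KO replicate 1 and 186 without its replicate 2. DESeq2 called 753 genes and limma voom 458, and 2061 had an unadjusted p below 0.05. The experiment and the control cannot be told apart in this comparison, so each knockout was read against its own control.

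Other lists that passed camera between the NK controls were type I interferon at -0.56 (1.78e-07; adjusted p = 0.558 with an estimated correlation), with 4 genes lower over all genes, neutrophil markers at -2.79 (1.72e-05; adjusted p = 0.411 with an estimated correlation), and endothelial markers at -3.93, or -3.06 at the bounds (0.000343; adjusted p = 0.278 with an estimated correlation). Interferon-gamma was at -0.14 (0.00493; adjusted p = 0.681 with an estimated correlation), cytokine signalling at 0.17 (0.0199; adjusted p = 0.67 with an estimated correlation), and maturation at 0.32 (0.00732) and dendritic markers at -0.48 (0.0466), for both of which adjusted p = 0.411 with an estimated correlation. Over all genes 9 B cell genes rose, and 11 macrophage and 13 chemokine genes fell. Without control-for-RSF1KO replicate 2, type I interferon was -0.16, interferon-gamma 0.23, cytokine signalling 0.35 and dendritic markers 0.11. Without control-for-RSF1KO replicate 1, interferon-gamma was -0.49 and dendritic markers -0.84. Without control-for-RNF2KO replicate 1, interferon-gamma was -0.01, cytokine signalling 0.41, dendritic markers -1.02 and endothelial markers -2.54, and without replicate 2 interferon-gamma was -0.31, maturation 0.20, cytokine signalling -0.01, neutrophil markers -1.77 and dendritic markers -0.11. The lists that did not pass were MHC class I (0.10), epithelial identity (-0.28), proliferation (0.11), hypoxia (-0.16), effectors (0.11), cytokines (-0.10), activating receptors (0.19), inhibitory receptors (-0.07), residency (0.16), early activation (0.04), oxidative phosphorylation (-0.19), and NK (0.23), T (0.26), fibroblast (0.09) and erythroid (-0.46) markers.

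The effects of the tumour labels on NK cells, each against its own control, differed from each other as lists. The largest of these differences mirrored those between the controls. That mirroring is partly built in, because the contrast contains the difference between the controls with its sign reversed. Bcl3 had a log2 difference between the RNF2KO and the RSF1KO effect of -2.88 ± 0.33 (n = 2 per group, edgeR adjusted p = 0.0595), Cd79a of -6.47 (adjusted p = 0.0595), Nfil3 of -2.56 (adjusted p = 0.0629) and Slamf8 of 4.67, none of which passed. B cell markers had a median difference of -6.89, or -5.78 at the bounds (camera adjusted p = 6.03e-35; adjusted p = 0.00507 with an estimated correlation), macrophage markers 3.62 (1.01e-21), chemokines 2.51 (8.79e-18) and early activation -0.34 (0.000182), for the last 3 of which adjusted p = 0.241 with an estimated correlation. Type I interferon was at 0.83 (5.61e-06; adjusted p = 0.594 with an estimated correlation), maturation at -0.46 (0.000271; adjusted p = 0.273 with an estimated correlation), epithelial identity at 1.67 (0.00108) and oxidative phosphorylation at 0.40 (0.00121), for the last 2 of which adjusted p = 0.681 with an estimated correlation. Cytokine signalling was at -0.38 (0.00154), neutrophil markers at 1.66 (0.00261) and T cell markers at -0.56 (0.0123), with adjusted p = 0.584 with an estimated correlation, and endothelial markers at 3.26 (0.0402) and inhibitory receptors at 0.16 (0.0393), with adjusted p = 0.539 with an estimated correlation. When adjusted over the list alone, 11 B cell genes were lower, 12 macrophage genes higher, and 16 chemokines higher with 1 lower. The lists that did not pass were MHC class I (0.01), interferon-gamma (0.11), proliferation (-0.20), hypoxia (0.01), effectors (-0.07), cytokines (-0.08), activating receptors (-0.04), residency (-0.12), and NK (-0.02), dendritic (0.04), fibroblast (0.00) and erythroid (-2.59) markers. No gene passed with edgeR, with 1419 at an unadjusted p below 0.05, 457 called by DESeq2 and 0 by limma voom, and 437 edgeR calls without RNF2KO replicate 1 and 256 without its replicate 2.

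Single libraries moved many of these differences. Leaving out NK RNF2KO replicate 1 gave macrophage markers 1.83, chemokines 1.36, type I interferon 0.26, epithelial identity 0.54, inhibitory receptors 0.41, oxidative phosphorylation 0.67, neutrophil markers 0.34 and endothelial markers 1.21. Leaving out its replicate 2 gave maturation -0.30, cytokine signalling -0.25, oxidative phosphorylation 0.10, inhibitory receptors 0.07 and T cell markers -1.13. Without control-for-RNF2KO replicate 1 early activation was -0.64 and cytokine signalling -0.62, and without its replicate 2 maturation was -0.30, cytokine signalling -0.05, oxidative phosphorylation 0.20 and neutrophil markers 1.09. Without NK RSF1KO replicate 1 epithelial identity was 0.85 and neutrophil markers 0.76, and without its replicate 2 they were 3.33 and 2.59. Without control-for-RSF1KO replicate 1 early activation was -0.58, cytokine signalling -0.17, T cell markers -0.999 and endothelial markers 2.08, and without its replicate 2 type I interferon was 0.50, epithelial identity -0.11 and neutrophil markers 0.78.

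ATAC-seq regions were open in some tumour groups and closed in others, with more loss than gain in the groups labelled RSF1KO and I53A. Of 93746 regions, 6681 were gained and 6898 lost in the group labelled RNF2KO, 4671 gained and 10116 lost in that labelled RSF1KO, and 1341 gained and 14209 lost in that labelled I53A, where gained means a peak in both libraries of the group and in neither control. A region over the start of the homeobox gene Irx3 (chromosome 8, 91801320 to 91802292, mm10) was gained in all 3 groups and one over Irx5 (8, 92357409 to 92357873) in those labelled RNF2KO and RSF1KO, as was a region over the start of Twist1, a mesenchymal regulator (12, 33956872 to 33958843). In the group labelled I53A the gained region of Irx5 lay 1080 bp from its start (8, 92355732 to 92356545). Regions near Krt5, a basal keratin (15, 101714512 to 101714774), and Ovol1, an epithelial regulator (19, 5561929 to 5562222), were lost in all 3 groups. Regions over the starts of Ctss (3, 95526646 to 95526900) and H2-DMb2 (17, 34143144 to 34143467), which act in MHC class II loading, were gained in the group labelled RNF2KO, and one over the start of Mmp3 (9, 7445654 to 7446190) was lost there and in the group labelled I53A. Of 24 hypoxia genes with a region, 4 had a gained region in the group labelled RNF2KO and 1 a lost one. Ankrd37 and Car9 were among those with a gained region, though their RNA was lower in that group. Of 25 epithelial identity genes with a region, 4, 6 and 7 had a lost region in the groups labelled RNF2KO, RSF1KO and I53A, and no list passed Fisher's exact test for gained or lost regions (adjusted p = 0.694, 0.193 and 0.282 for that list).

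With 2 libraries against 2, the ATAC counts allow no test below a share of 1 in 3 splits. The splits that mix the groups gave at most 964 regions for the group labelled RNF2KO, 814 for RSF1KO and 917 for I53A. The control and RNF2KO files carried a different tag total in their headers from the RSF1KO and I53A files, so the last groups cannot be told apart from a processing run when set against the control. The lists also differed in length, with 73253 and 70466 peaks in the control, 72514 and 70125 for RNF2KO, 64164 and 62793 for RSF1KO, and 56614 and 48708 for I53A. With every list at the length of the shortest, 4607 regions were gained and 4686 lost for RNF2KO, 4853 and 5011 for RSF1KO, and 4173 and 5196 for I53A. Lists of equal length bring gained and lost counts close together by construction. This setting therefore cannot decide whether the excess of loss reflects more than list length. Leaving out RNF2KO replicate 2 gave 10629 gained regions, leaving out control replicate 2 gave 11439 lost regions, and for RSF1KO leaving out its replicate 2 gave 7089 gained regions and leaving out control replicate 2 gave 15470 lost regions. For I53A, leaving out its replicate 2 gave 3590 gained regions and leaving out control replicate 2 gave 2042.

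Lost regions, and gained regions of the groups labelled RNF2KO and RSF1KO, were shared between groups beyond the simulated value. The simulation drew each region from its control peaks alone, without peak strength or list length. It therefore cannot separate a shared change of chromatin from an effect of either. Those labelled RNF2KO and RSF1KO shared 2726 gained and 5434 lost regions. Unchanged groups simulated against the shared controls shared 1057 and 455 (highest 1172 and 502), and independent lists would share 338 and 756. The simulated lists were shorter than those of this pair, so the simulated counts cannot be set directly against the observed counts. As a share of the smaller list, the gained overlap was 58.4% for RNF2KO with RSF1KO, 48.4% for RNF2KO with I53A (649 regions) and 39.2% for RSF1KO with I53A (525), against 45.8% in the simulation. That value was the same for every pair and not matched to list length, so it sets no level for the overlaps with I53A. The lost overlap was 78.8%, 80.6% (5561) and 70.8% (7158), against 19.8%. All 3 shared 386 gained and 4559 lost regions. The simulated groups shared their controls too, so the simulated value already holds that part under its setting. The controls were not split, and the overlap was not computed with lists of equal length. Set against each other within a tag total, the groups labelled RSF1KO and I53A differed at 9628 regions open in RSF1KO alone and 2229 open in I53A alone. With lists of equal length, which bring these counts together by construction, they differed at 5354 and 4357. At full length, the regions open in I53A alone were 5650 without I53A replicate 2 and 3298 without RSF1KO replicate 1.

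**Figure D4:**
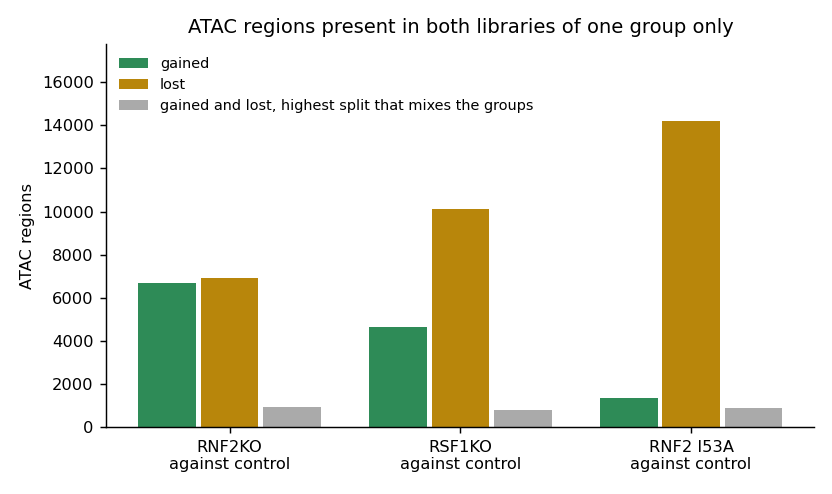
Number of ATAC regions (y axis) gained and lost in each group against the control, beside the highest number from splits that mix the groups. Lost regions numbered 6898, 10116 and 14209, against at most 964 in a mixed split.

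RNF2 in cultured 4T1 cells occupied gene starts, among them those of epithelial genes. The 2 replicates held 6673 and 4832 peaks, and 3546 regions had a peak in both, of which 73.6% (2608) lay within 2000 bp of a gene start and 94.8% overlapped an ATAC region. Bound starts included Cdh1, the epithelial cadherin (chromosome 8, 106602777 to 106604444, mm10), Bmi1, a PRC1 subunit (2, 18677696 to 18678586), and Odc1 (12, 17544988 to 17545614). By the summed ranks of the authors' fold enrichment in both replicates, the strongest shared peaks were nearest to Tle4 (19, 14620311 to 14620905, 41.7 and 38.4), Fam180a (6, 35323050 to 35323776, 35.2 and 38.6) and Fbxo21 (5, 117988025 to 117989126, 38.05 and 37.1), each more than 2000 bp from the gene start, followed by Spop (11, 95413588 to 95413981, 39.2 and 34.9) at 295 bp. Of 26 epithelial identity genes, 13 were bound, against 6.54% of other genes (Fisher's exact test, two-sided, adjusted p = 4.71e-08), including Epcam, Krt7 and Ovol1. Of 28 polycomb components, 10 were bound (adjusted p = 7.98e-05), and so were 8 of 32 proliferation genes (0.00718), 7 of 27 hypoxia genes (0.00898), 6 of 23 p53 genes (0.0152) and 5 of 21 MHC class I genes (0.0424). That background holds genes that are not expressed. Among the 16298 genes with a symbol tested in the tumour cells, a background chosen after the data were seen like these list tests themselves, 16.6% of the others were bound, and only epithelial identity passed (odds ratio 5.02, Fisher's exact test adjusted p = 0.00224). The polycomb components were then at 0.222, MHC class I at 0.690, and proliferation, hypoxia and p53 each at 0.679. The developmental transcription factors, of the kind that PRC1 silences in many cells, were bound at 6 of 87 (unadjusted p = 0.828), with Foxa1, Irx2 and Meis1 among them, and no MHC class II gene of 11 was bound.

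RNF2-bound sites seldom lay in ATAC regions called gained or lost. In the group labelled RNF2KO, 10 of 6681 gained regions (0.150%) overlapped a bound peak, against 4.93% of the others (Fisher's exact odds ratio 0.0289), as did 33 of 6898 lost regions (0.478%, odds ratio 0.0931). Changed regions held weaker peaks, and within 5 strata of peak strength the odds ratios were 0.171 (Cochran-Mantel-Haenszel adjusted p = 3.65e-08) and 0.508 (0.00023). For RSF1KO the ratios were 0.0243 for gained and 0.0799 for lost, and 0.132 and 0.388 within strata. For I53A they were 0.0835 and 0.0495, and 0.472 (adjusted p = 0.0934) and 0.152 within strata. The strata were chosen after the data were seen. Gained regions by definition had no peak in the control tumours, while 94.8% of bound regions overlapped an ATAC region. Part of the scarcity in gained regions may thus be built in, and the strata do not remove that part. A region that changed in height but kept its peak counts as unchanged here. These ratios therefore do not show that chromatin at bound sites stayed the same.

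Since no tumour gene passed its adjusted threshold, the planned tests of bound genes had no genes to test, and genes at an unadjusted p below 0.05 were used instead, a choice made after the data were seen. Genes with RNF2 at their start were scarce among the higher genes and frequent among the lower ones. In the group labelled RNF2KO, 89 of 1505 higher genes (5.91%) were bound against 17.7% of the rest (odds ratio 0.292, Fisher's exact test adjusted p = 1.36e-38), and 251 of 904 lower genes (27.8%, odds ratio 2.02, 5.82e-18). Within 5 strata of expression these odds ratios were 0.328 and 1.56. The higher genes of this group include those of a library with 724 CPM of T cell markers, against 18.3 to 28.4 elsewhere. Among lower genes in the group labelled RSF1KO, 309 of 899 were bound (34.4% against 15.6%, odds ratio 2.83). The 835 of these lower genes measured in NK cells had medians of 0.69 in NK RSF1KO and -0.64 in NK RNF2KO, each against its control. Odc1, Jund, Rnf187, Mmp14 and Ndrg1 were among the bound genes with lower values. Bound genes as a set had a median of -0.17 for RNF2KO (camera adjusted p = 0.000897; adjusted p = 0.373 with an estimated correlation) and -0.16 for RSF1KO (0.000228; adjusted p = 0.430 with an estimated correlation). Genes with a gained ATAC region at their start were frequent among the higher genes, at 136 of 797 (17.1% against 3.50%, odds ratio 5.67, adjusted p = 1.77e-45) for RNF2KO and 42 of 393 (10.7% against 3.32%, 3.49, 5.87e-10) for RSF1KO. As a set, genes with a region gained in RNF2KO had a median of 0.95 in that group (camera adjusted p = 1.24e-06, and 0.373 with an estimated correlation). Those with a region gained in RSF1KO had a median of 0.53 in RSF1KO (camera adjusted p = 0.000412, and 0.430 with an estimated correlation). The latter genes had a median of 1.03 in RNF2KO, so the link was not tied to the matching group. Lost regions and lower genes had odds ratios of 1.53 (Fisher's exact test adjusted p = 0.0564) and 1.20 (adjusted p = 0.257). Genes are not independent replicates in these tests.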

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

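Of the tests in this part, the one for a control library with a wrong label was planned before its result was seen, and the rest were chosen only after the result was seen.

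The library labelled RNF2KO replicate 2 held leukocyte transcripts, and its Rnf2 was the highest of the tumour-cell libraries. Its marker sums were 25.5 times the highest other library for T cells, 10.5 for NK cells, 4.62 for macrophages and 1.02 for dendritic cells, whose median member was nonetheless at 10.07 CPM against 0.39 to 1.75 elsewhere. Leukocytes passing the FACS gate on tumour cells would raise genes of the NK profile outside the marker lists too, and 97% of 100 such genes were at least 2 times above every other tumour-cell library, which fits. A control library with a wrong label would follow the controls over 1726 genes that separate replicate 1 from RSF1KO, and the median signed difference was -0.37, which cannot tell. The Rnf2 level of replicate 1 plus that of leukocytes like NK cells would reach 19.2 normalised CPM (10.7 from leukocytes) against 45.1 observed, which cannot tell either because the profile was assumed. Leukocytes may therefore account for the marker lists, while the Rnf2 level remains open.

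The NK libraries differed in B cell and myeloid transcripts, both within the RNF2KO experiment and between its controls and those of RSF1KO. Other leukocytes in the NK libraries remain open, because the 12 of 12 B cell markers that were lower, with an NK marker median of 0.08, restate the pattern and decide nothing. A smaller share of NK cells would raise all other types alike, but the macrophage median minus the B cell median was 7.42. A difference between the experiments alone would leave the B cell list unchanged inside one of them, but its median there was -4.87.

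The 835 genes lower in the tumour cells labelled RSF1KO and measured in NK cells moved together in NK libraries. An effect of RSF1 loss in tumour cells alone would leave them unchanged in NK cells. Their median was 0.69 in NK RSF1KO against its control, with random sets between -0.03 and 0.04. It was also -0.64 in NK RNF2KO against its control and 0.33 between the NK controls, each beyond the random sets. These sets were matched on expression and not on correlation between genes, and every comparison and replicate difference lay beyond them. The test therefore cannot decide on an effect of RSF1 loss alone. A property of single libraries would separate replicates. All 4 NK groups were beyond the random sets, and 2 of them by more than 0.3 as the test required, at 0.51 in RSF1KO and -0.62 in RNF2KO, with -0.10 and -0.29 in their controls. Transcript length could act on both cell types, but the median was 0.64 after its trend was removed. The replicate differences were set against the same random sets, so a property of library preparation remains open. Whether it has a part in the fall of Odc1, Taf10 and Jund was not tested by gene, and the cause was not tested further.

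Measured against the own control of each, the RNF2KO and RSF1KO labels had opposite or unequal values for 13 of 25 lists in NK cells, 1 of them with an estimated correlation. The differences of median effects were 0.83 for type I interferon, 2.51 for chemokines, 1.67 for epithelial identity, 0.16 for inhibitory receptors, -0.46 for maturation, -0.34 for early activation, -0.38 for cytokine signalling and 0.40 for oxidative phosphorylation. For markers they were -0.56 for T cells, -6.89 for B cells, 3.62 for macrophages, 1.66 for neutrophils and 3.26 for endothelial cells. The largest mirror the medians between the controls, which were 6.38 for B cells, -4.46 for macrophages and -3.22 for chemokines. That is partly built in, because the contrast contains the difference between the controls with its sign reversed. The B cell sums were 139 and 172 CPM in RSF1KO and 200 and 206 in RNF2KO.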

How the results depend on the processing

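Limma voom, the -log10 q of 20, the ATAC comparisons between knockout groups, the genes at unadjusted p, the strata of peak strength, the binding of gene lists with both backgrounds, the NK lists without the genes lower in tumour RSF1KO and the overlap with 1 library left out are tests chosen only after the result was seen. So were the strata of expression for ATAC regions at changed genes. The other alternatives were fixed before the data were examined. The cause was not tested for any of these shifts.

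With DESeq2, 871 genes were called in tumour RNF2KO against control, 496 in RSF1KO against control, 263 between them, 334 in NK RNF2KO, 66 in NK RSF1KO, 457 for the NK difference and 753 between the NK controls. Without a filter, edgeR called 1367, 615, 643, 691, 422, 910 and 1115. Limma voom called 147 genes in tumour RSF1KO and 0 in NK RNF2KO. A fit of the compared groups only called 113 in tumour RSF1KO, 0 in NK RNF2KO and 654 between the NK controls, and the stricter filter left 9 in NK RNF2KO.

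A replicate block, which takes the same replicate number as shared between groups, left 5 genes in NK RNF2KO. The numbers may share only a number, and no crossing of animals or batches is stated.

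Lists past camera numbered 14, 9, 10, 14, 11, 13 and 10 in the same order, 0, 0, 0, 2, 0, 1 and 1 with an estimated correlation, and 0, 0, 0, 2, 0, 1 and 2 with fry.

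With 1 library left out, edgeR calls ran from 0 to 1572 in tumour RNF2KO, 0 to 443 between the tumour groups, 0 to 432 in NK RNF2KO, 0 to 437 for the NK difference and 72 to 186 between the NK controls. The correlation of the tumour effects ran from 0.43 to 0.68, and was 0.40 or 0.38 with the controls split.

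For ATAC, leaving out 1 library gave 8465 to 10629 gained and 8453 to 11439 lost regions in RNF2KO, 5807 to 7089 and 12123 to 15470 in RSF1KO, and 1714 to 3590 gained in I53A. Lost regions ran from 2802 to 5650 for RSF1KO against I53A and 1599 to 3194 for RNF2KO against I53A, and RNF2KO against RSF1KO from 8724 to 10993 gained and 2765 to 3852 lost. A -log10 q of 20 left 2960 gained in RSF1KO, 719 in I53A and 698 lost in RNF2KO against I53A. A -log10 q of 5 removed nothing.

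With equal lengths, which bring gained and lost counts together by construction, 5011 regions were lost in RSF1KO, and 4173 gained and 5196 lost in I53A. Between groups there were 5354 and 4357 for RSF1KO against I53A, 2780 gained for RNF2KO against RSF1KO, and 4851 and 3719 for RNF2KO against I53A. Within 1000 bp of gene starts, gained regions at lower genes had odds ratios of 0.432 in RNF2KO (adjusted p = 0.0095) and 0.506 in RSF1KO, lost regions 1.76 at lower genes in RNF2KO and 1.92 at higher genes in RSF1KO. Within strata the odds ratio was 1.62 for lost regions at lower genes in RNF2KO, and 0.472 for bound regions gained in I53A. With tested genes as background, odds ratios of RNF2 binding were 2.78 for polycomb components, 1.67 for proliferation, 1.75 for hypoxia, 1.88 for p53 and 1.56 for MHC class I, none past the threshold.

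Some signs turned with 1 library left out, given here as lowest and highest median. In tumour RSF1KO proliferation ran from -0.759 to 0.086, positive without RSF1KO replicate 1. Between the tumour groups, markers ran from -1.963 to 3.499 for NK, -0.142 to 4.947 for T, -0.263 to 3.371 for neutrophils and -0.074 to 3.856 for dendritic cells, negative without RNF2KO replicate 2. In NK RNF2KO, type I interferon ran from -0.007 without its replicate 1 to 0.639, and cytokine signalling from -0.316 to 0.054 without control replicate 2. Without control-for-RSF1KO replicate 2 the sign turned for type I interferon (-0.612 to 0.061), epithelial identity (-3.422 to 0.254) and cytokines (-0.421 to 0.015) in NK RSF1KO, for epithelial identity in the NK difference (-0.106 to 3.331), and for interferon-gamma (-0.493 to 0.234) and dendritic markers (-1.019 to 0.106) between the controls. Cytokine signalling between the controls ran from -0.009 without control-for-RNF2KO replicate 2 to 0.407.

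Rnf2 in tumour RNF2KO was -0.166 with the replicate block, whose numbers may share only a number, -0.129 with limma voom, -1.484 without RNF2KO replicate 2 and 0.862 without replicate 1. Rsf1 in tumour RSF1KO was -0.464 without RSF1KO replicate 1 and 0.598 without replicate 2. Nkg7 in tumour RNF2KO was -0.713 without RNF2KO replicate 2 and 4.947 without replicate 1.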

Other observations

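Across chromosomes, chromosome 14 had the lowest share of gained among changed ATAC regions in the group labelled RNF2KO, with 119 gained and 409 lost (22.5%), and 13.1% in RSF1KO and 4.1% in I53A. Its genes had the lowest median log2 fold changes of RNA as well, at -0.34 in the tumour cells labelled RNF2KO and -0.21 in those labelled RSF1KO. On chromosome 10, 32.8% of changed regions were gained, while its RNA median was 0.15.

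Changed ATAC regions lay away from gene starts. In the group labelled RNF2KO, 13.9% of gained and 10.6% of lost regions were within 2000 bp of one, against 28.2% of kept regions. In RSF1KO 15.3% of gained and 29.7% of kept regions were, and in I53A 17.5% and 32.3%. Regions near Phc2, a PRC1 subunit (chromosome 4, 128654530 to 128654928), were gained in RNF2KO and RSF1KO. A region near Car9 (4, 43508590 to 43508980) was gained in all 3 groups, and the one over its start (4, 43506608 to 43507248) was lost in I53A. Car9 RNA was below the control in the tumour cells labelled RNF2KO.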
